A study of Homo sapiens with 9 samples.

How the data were processed

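The data are 9 RNA sequencing libraries, 3 for each of 3 times of exposure to 1 nM sAPPα (0 h, 0.5 h and 2 h), from neurons differentiated from the WTC-11 line with 10 µM doxycycline for 3 days and grown in medium with 10 ng/mL BDNF to day 18. Per the labels' protocols, RNA had an integrity number above 9.5, rRNA was removed, libraries were made with a stranded total RNA kit, and paired reads of 100 bp were sequenced on several lanes. Groups were taken from the sample titles. The labels give no libraries that received medium without sAPPα for 0.5 h or 2 h.

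The deposited table holds raw read counts for 60671 genes. Per the file headers, the authors counted reads with featureCounts 2.0.1 on the exons of Ensembl release 101 (GRCh38), from 1 merged alignment file per library. The command in the header sets neither paired-end nor strand options nor multi-mapping, so both ends of a pair were counted singly, reads from the opposite strand were included, and reads matching several places or overlapping several genes were not counted. Genes that overlap another gene or have near-identical copies are therefore less certain, and multi-copy rRNA genes are hardly counted. Per the submitters' processing notes, Trimmomatic, STAR, SAMtools, MultiQC, Subread, limma and edgeR were also used, and their versions are not given in the sources used here. Gene symbols came from a GENCODE name table, in which 60401 of the 60671 identifiers were found. All coordinates are those of the deposited table.

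Totals ranged from 57853197 to 77773590 counts, and counting single ends means that these are about read ends, not fragments. The biological coefficient of variation was 8.2%. Within groups, pairs of libraries differed by 9.40 to 28.2 times the chi-square expected from sampling alone, so no library was taken as a copy of another.

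Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups (25271 genes), libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 9 libraries (6 residual degrees of freedom). The contrasts were 0.5 h against 0 h, 2 h against 0 h and 2 h against 0.5 h, with a joint test of the 3 times. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. The SE of a log2 fold change was the change divided by the root of its F statistic. CPM values are TMM-scaled.

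Gene lists (38, with 1071 symbols tested) and cell type markers were fixed before the data were examined. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 114 tests, and again with an estimated correlation and with fry. Camera called 33 of the 114 tests. None of them passed with an estimated correlation, and fry called none in 1 direction. The lists with no camera call in any contrast were delayed activity response genes, APP family and processing, ionotropic glutamate receptors, GABA receptors, NF-κB targets, antioxidant response, hypoxia and glycolysis, translation factors, ribosomal proteins, replication-dependent histones, nuclear noncoding RNAs and the markers of astrocytes, oligodendrocytes, microglia, mesenchymal and peripheral neuronal cells.

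The rule for named genes was also fixed before the data were examined. It took, per contrast, the 8 genes with the largest rise and the 8 with the largest fall among those that passed, had a symbol, a mean of at least 1 CPM and non-overlapping replicates, or the 10 smallest p where fewer than 10 passed, up to 4 members of each list with a camera call, and 14 fixed genes. Y-linked genes and XIST were left out, and not every gene that the rule takes is given in the text. Outside the rule, IER2, SPRY1, CSRNP1, BACH2, RAB3B, PSMD12 and DUSP10 at 0.5 h, and the 0 h levels of NAB2 and SREBF1, are named because of their values, chosen after these were seen.

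The model was tested on simulated counts with the real means, dispersions and library sizes, with 250 changed genes per fold over 5 simulations (500 over 10 for 2 h against 0.5 h). For 0.5 h against 0 h, over 25271 genes, 11.2% of genes changed 1.2-fold, 47.2% of those changed 1.5-fold, 61.6% of those changed 2-fold and 89.6% of those changed 4-fold were recovered, and 6.76% of the calls were false. For 2 h against 0 h the shares were 15.6%, 48.4%, 61.2% and 90.8%, with 10.6% of calls false. For 2 h against 0.5 h they were 13.0%, 47.6%, 62.4% and 89.2%, with 7.74% false. A GC trend put into the simulated 0.5 h libraries gave 6970 false calls without offsets for GC content and length and 0 with them.

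Alternatives were DESeq2 size factors, upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, only the 2 groups compared, a replicate block, non-robust estimation, a minimum log2 change of 0.26, an adjusted p of 0.01 and leaving out each library. Added after seeing the data were offsets per library for GC content and length (GC content of the longest GENCODE transcript, known for 97.4% of tested genes), the same with the replicate block, leaving out mitochondrial, 7SL and U3 genes, halving the counts, and leaving out both libraries with high mitochondrial rRNA.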

Results

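RNA was sequenced from human glutamatergic neurons made from WTC-11, an established induced pluripotent stem cell line that carries a doxycycline-inducible NGN2 gene, the transcription factor that drives the cells into a neuronal fate. On culture day 18 the neurons received 1 nM sAPPα, the soluble fragment released when alpha-secretase cleaves the amyloid precursor protein. The exposure lasted 0 h, 0.5 h or 2 h, and the culture day was the same for all libraries. There were 3 libraries per time. Total counts assigned to genes ranged from 57853197 to 77773590 per library. The values below are CPM, read counts normalised to library size (mean ± SD, n = 3), and log2 fold changes with their standard errors (SE). The labels describe 1 line and do not say whether the replicates were separate wells, plates or cultures. The p-values therefore measure the spread between these libraries only.

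The first comparison asked which transcripts differed after 0.5 h of sAPPα. The largest rise was that of EGR1, an immediate early transcription factor induced by growth factor and synaptic signals, from 3.31 ± 0.672 CPM at 0 h to 10.97 ± 2.12 CPM at 0.5 h (log2 fold change 1.73, SE 0.16, adjusted p = 5.0e-05, edgeR). FOS, a subunit of the AP-1 transcription factor, rose from 28.1 ± 2.19 to 57.1 ± 7.81 CPM (log2 1.02, SE 0.09). SPRY2 and DUSP6, both feedback inhibitors of ERK signalling, rose by log2 0.71 (SE 0.06) and 0.50 (SE 0.05). KLF10, a transcription factor first described as induced by TGF-β, fell from 13.7 ± 1.44 to 7.46 ± 0.482 CPM (log2 -0.88, SE 0.11, adjusted p = 0.0012). Of 25271 genes tested, 218 passed an adjusted p of 0.05, 41 higher and 177 lower.

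The immediate early gene list held 35 tested members, of which 5 rose and 2 fell. CCN1 (log2 0.94, SE 0.14) and CCN2 (log2 0.55, SE 0.09), secreted matrix-associated proteins, rose with EGR1, FOS and IER2 (log2 0.41, SE 0.08), and KLF10 and CSRNP1 (log2 -0.58) fell. The counts adjusted over the list alone were 8 and 4. The camera test placed the list above the other genes (adjusted p = 0.020), and the call was lost with an estimated correlation between genes (adjusted p = 0.85 with an estimated correlation). Among 18 ERK feedback genes, DUSP6, SPRY2 and SPRY1 (log2 0.36, SE 0.07) rose and none fell. With p adjusted over the list alone 3 rose and 3 fell, and camera did not call the list (adjusted p = 0.078). ADM, which encodes the vasodilator peptide adrenomedullin, rose from 4.39 ± 0.707 to 7.85 ± 0.791 CPM and was the only one of 31 hypoxia and glycolysis genes that passed.

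**Figure D1:**
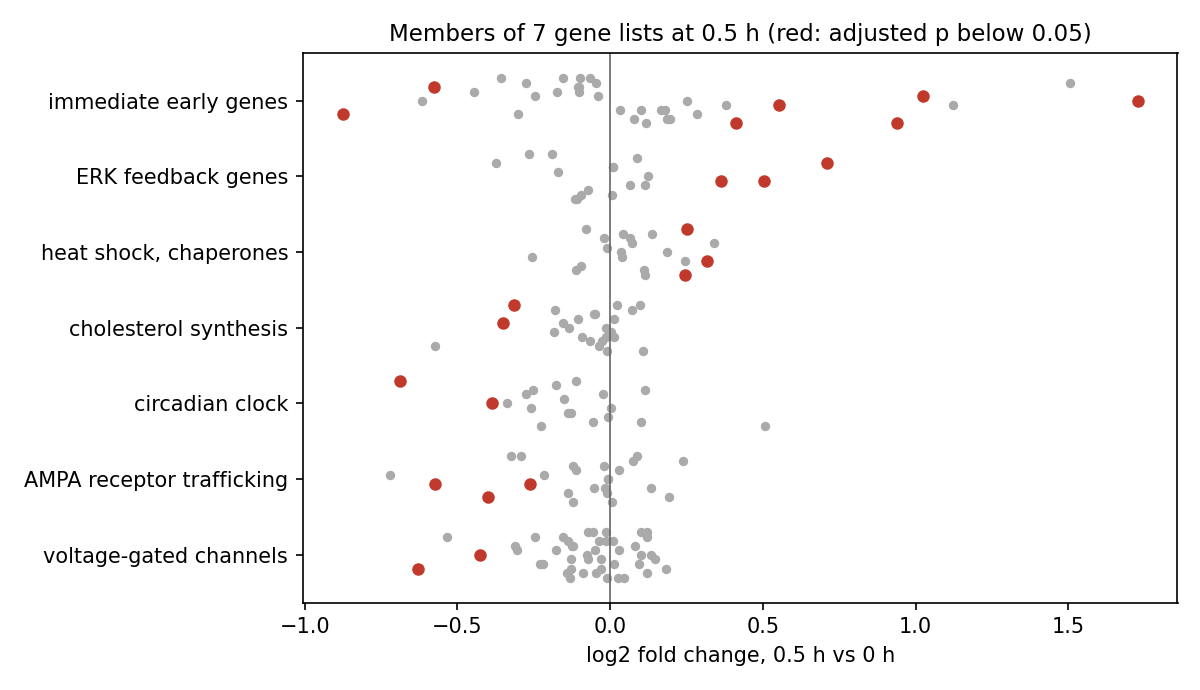
Log2 fold change at 0.5 h against 0 h (horizontal axis) of each tested member of 7 gene lists, 1 line per list, with vertical offsets only to separate points and members past an adjusted p of 0.05 in red. The red points of the immediate early list lie on both sides of 0, from -0.88 (KLF10) to 1.73 (EGR1), whereas those of the heat shock list lie above 0 and those of the cholesterol and circadian lists below it.

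Of 20 heat shock and chaperone genes, 3 rose and none fell. HSPA8, the constitutive HSP70 chaperone, rose from 3103 ± 50.5 to 3676 ± 57.8 CPM (log2 0.24, SE 0.04), HSPA1A rose by log2 0.25 (SE 0.05) and CHORDC1 by log2 0.32 (SE 0.07). HSPA1A shares most of its sequence with HSPA1B, so its level is uncertain. There were 7 that rose when adjusted over the list alone. Camera called the list higher (adjusted p = 0.00091), with an adjusted p of 0.85 with an estimated correlation. Among 24 cholesterol synthesis genes, SREBF2, the transcription factor that drives the pathway, fell from 192 ± 20.9 to 151 ± 2.19 CPM (log2 -0.35, SE 0.06). In this list 5 fell when adjusted over the list alone. In the circadian list, TEF (log2 -0.39, SE 0.08) and BHLHE40 (log2 -0.69, SE 0.15) fell among 19 tested members, and 5 fell when adjusted over the list alone. Camera called both lists lower (adjusted p = 0.0059 for cholesterol synthesis and 0.0068 for the circadian list). These calls too were lost (adjusted p = 0.85 and 0.83 with an estimated correlation).

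Some of the genes that fell belonged to the lists of AMPA receptor trafficking, voltage-gated channels and insulin and mTOR signalling. In the AMPA receptor trafficking list, 3 of 24 members fell: CACNG8, an auxiliary subunit of AMPA receptors, from 33.5 ± 2.46 to 22.5 ± 1.99 CPM (log2 -0.57, SE 0.09), NPTX1 (log2 -0.26, SE 0.05) and NPTXR (log2 -0.40, SE 0.09), which encode pentraxins that cluster these receptors. Among 45 voltage-gated channel genes, the potassium channel gene KCNA2 (log2 -0.63, SE 0.09) and the pacemaker channel gene HCN4 (log2 -0.43, SE 0.09) fell. In the list of insulin, IGF, PI3K and mTOR signalling, IGF1R, GSK3A and EIF4EBP2 fell among 36 members. Adjusted over the list alone, 4 members fell in each of these 3 lists, and 1 AMPA receptor trafficking gene rose. None of 42 postsynaptic density genes passed over all genes, whereas 10 fell and 1 rose when adjusted over that list alone. Camera called these 4 lists lower (adjusted p from 0.039 to 0.047). With an estimated correlation the adjusted p was 0.85 for AMPA receptor trafficking, 0.88 for the channels and 0.86 for each of the others.

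In the mitochondrially encoded list, MT-CO2 and MT-CO3, subunits of cytochrome c oxidase, fell from 189 ± 14.97 to 134 ± 15.3 CPM and from 564 ± 34.0 to 370 ± 57.1 CPM among 15 members, and 4 fell when adjusted over the list alone. The list's median log2 change was -0.16 and its mean 0.05, while camera called it lower (adjusted p = 0.00091, and 0.85 with an estimated correlation). Mitochondrial rRNA was high in single libraries, with 0.539% of the counts in 0.5 h replicate 3 (95% Wilson interval 0.537 to 0.540%), 0.207% in 0 h replicate 3 (0.206 to 0.208%) and from 0.0963% to 0.126% in the others. The intervals cover counting error only. The core spliceosome list was also called lower (adjusted p = 0.0097, and 0.86 with an estimated correlation), with HNRNPA1 the only one of 40 members that fell (log2 -0.45, SE 0.09), a gene with many processed pseudogenes whose level is therefore uncertain. In all, 8 fell when adjusted over the list alone.

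Other large decreases at 0.5 h were those of C7orf31 (log2 -0.95, SE 0.19), the vault RNA VTRNA1-3 (log2 -0.90, SE 0.15), the protocadherin PCDHGB2 (log2 -0.87, SE 0.20), the arrestin-domain gene ARRDC4 (log2 -0.82, SE 0.16), the amino acid transporter SLC7A8 (log2 -0.82, SE 0.17), E2F8 (log2 -0.80, SE 0.13) and ADAMTS8 (log2 -0.74, SE 0.15). ZNF404 rose by log2 0.51 (SE 0.11). PCDHGB2 shares 45.7% of its exonic bases with other protocadherin genes, so its level is uncertain. VTRNA1-3 has 89 exonic bases, fewer than the 100 bp of a read, so its level is uncertain too. Several genes often followed after synaptic activity did not pass. The log2 fold change was -0.10 (SE 0.21) for ARC, -0.10 (SE 0.14) for NR4A1, 0.14 (SE 0.08) for BDNF, 0.09 (SE 0.05) for HOMER1 and 1.12 (SE 0.38) for NPAS4, which was at 0.355 ± 0.153 and 0.785 ± 0.372 CPM (adjusted p = 0.19). APP itself was at 940 ± 37.0 and 1021 ± 53.5 CPM (log2 0.12, SE 0.05, adjusted p = 0.32). GRIA1, GRIN2B, CAMK2A, DLG4, SYN1 and SYP, which encode glutamate receptor subunits, a kinase and synaptic proteins, had log2 values from -0.34 (SYN1) to 0.15 (SYP), with adjusted p from 0.188 (SYP) upward.

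The median absolute log2 change of the 218 genes was 0.37, and 4 changed at least 2-fold. All 218 had non-overlapping replicate values, as did 18.9% of all tested genes, where chance gives 10%. The count was 104 without 0 h replicate 1, 45 without 0 h replicate 2, 141 without 2 h replicate 3, and 57, 72 and 47 without 0.5 h replicates 1, 2 and 3, with 9 of the higher and 19 of the lower genes called whichever library was left out. Among the genes named above that passed at 0.5 h, EGR1, FOS, SPRY2, DUSP6, KLF10 and CACNG8 passed under each alternative run for named genes, and the others chosen by the fixed rule lost the call under at least 1. The share of lower calls depended on the settings. It was 81.2%, against 69.7% with upper-quartile scaling, 64.7% with the replicate number as a block and 64.9% with offsets for GC content and length. With offsets and block together the higher calls outnumbered the lower (751 and 621). The offsets were chosen after seeing the data. With the offsets alone, MT-CO2, MT-CO3, NPTXR, HCN4, IGF1R, PCDHGB2 and ZNF404 no longer passed.

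The second comparison asked which transcripts differed after 2 h. No gene passed an adjusted p of 0.05 in edgeR (smallest 0.053), while 1460 genes had an unadjusted p under 0.05, where 1264 would be expected by chance. DESeq2 called 92 genes, 91 of them lower, edgeR without a low-count filter 211, 205 of them lower, and limma-voom 0. With the replicate number as a block, edgeR called 104 genes, 97.1% of them lower. The labels do not say what the replicate numbers stand for. Several genes with a small p were lower at 2 h without passing. Among them, XYLT1, which starts glycosaminoglycan chains on proteoglycans, was at 30.0 ± 3.62 CPM at 0 h and 21.02 ± 0.444 CPM at 2 h (log2 -0.52, SE 0.08, adjusted p = 0.062). Others were the tyrosine kinase gene SRC (log2 -0.40, SE 0.07), the dendritic spine protein gene PPP1R9B (log2 -0.38, SE 0.06), UBXN7 (log2 -0.40, SE 0.07), CACNG8 (log2 -0.52, SE 0.09) and MAVS (log2 -0.40, SE 0.07), also with adjusted p of 0.062. KCNA2 (log2 -0.59, SE 0.09), KIRREL1 (log2 -0.44, SE 0.08) and ZXDB (log2 -0.57, SE 0.10) followed at 0.086. FOS (log2 0.03, SE 0.09) and EGR1 (log2 -0.29, SE 0.17) were near their 0 h levels, and ARC, NR4A1, NPAS4, BDNF, HOMER1, GRIA1, GRIN2B, CAMK2A, DLG4, SYN1, SYP and APP had adjusted p from 0.838 (SYN1) upward.

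At 2 h, 10 lists were called lower by camera and 2 higher, with no member passing over all genes. None of the 12 calls held with an estimated correlation (adjusted p from 0.83 to 0.88 with an estimated correlation). The lower lists were voltage-gated channels (median log2 -0.10, adjusted p = 4.6e-06), presynaptic vesicle release (-0.07), insulin and mTOR signalling (-0.07), postsynaptic density (-0.03), glutamatergic neuron markers (-0.06), histone acetylation and methylation enzymes (-0.03), AMPA receptor trafficking (-0.05), mitochondrially encoded genes (-0.13), neurotrophin signalling (-0.04) and neural progenitor markers (-0.04). Nuclear oxidative phosphorylation genes (0.05) and proteasome genes (0.04) were called higher. In the oxidative phosphorylation list 63 of 75 members had a positive log2 value, and in the proteasome list 29 of 36. The member with the smallest p was nevertheless lower in both lists, ATP5F1B (log2 -0.12, SE 0.04) and PSME3 (log2 -0.17, SE 0.06). Examples of the lower lists are SV2C (log2 -0.34, SE 0.09), RAB3B (log2 -0.28, SE 0.06), SHANK3 (log2 -0.29, SE 0.09), IRS1 (log2 -0.21, SE 0.06), NEFM (log2 -0.21, SE 0.06), DCX (log2 -0.26, SE 0.07) and CREBBP (log2 -0.25, SE 0.08), with adjusted p from 0.139 (RAB3B) to 0.472 (IRS1). Adjusted over the list alone, 1 channel, 3 presynaptic, 4 insulin and mTOR, 1 postsynaptic, 3 glutamatergic marker, 2 AMPA receptor trafficking and 2 mitochondrial genes fell. The count of 0 became 33 without 0 h replicate 3, 40 without 2 h replicate 1, 1 without 2 h replicate 3 and 11 without 0.5 h replicate 2, all lower.

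The third comparison set 2 h directly against 0.5 h, in a contrast that does not use the 0 h level, and asked which genes changed between the exposures. The test found 11 genes, whose log2 values at 2 h against 0 h lay between -0.29 (EGR1) and 0.14 (CSRNP1). In GRCh38 coordinates, 7 genes were lower at 2 h than at 0.5 h. EGR1 (chromosome 5, 138465479 to 138469303) went from 10.97 to 2.70 ± 0.311 CPM (log2 -2.02, SE 0.17, adjusted p = 1.4e-05), FOS (chromosome 14, 75278826 to 75282230) from 57.1 to 28.7 ± 2.15 CPM (log2 -0.99, SE 0.09) and SPRY2 (chromosome 13, 80335976 to 80341126) from 164 to 103 ± 2.94 CPM (log2 -0.67, SE 0.06). DUSP6 (chromosome 12, 89347235 to 89352501) had log2 -0.49 (SE 0.05), CCN1 (chromosome 1, 85580761 to 85584589) -0.98 (SE 0.14), ADM (chromosome 11, 10305073 to 10307397) -0.85 (SE 0.13) and CCN2 (chromosome 6, 131948176 to 131951372) -0.54 (SE 0.09). The counts cover annotated exons, and 28.6% of the exonic bases of DUSP6 overlap another gene.

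The other 4 genes were lower at 0.5 h than at both other times. NAB2 (chromosome 12, 57089043 to 57095476), a corepressor that binds EGR proteins, was at 72.4 ± 0.852 CPM at 0 h, 47.0 ± 0.826 at 0.5 h and 70.5 ± 2.09 at 2 h (log2 0.58 between 0.5 h and 2 h, SE 0.05, adjusted p = 1.4e-05). KLF10 (chromosome 8, 102648784 to 102655725) rose between 0.5 h and 2 h by log2 0.99 (SE 0.11), CSRNP1 (chromosome 3, 39141855 to 39154562), a nuclear protein gene inducible by axin, by 0.72 (SE 0.09), and SREBF1 (chromosome 17, 17810399 to 17837011), a transcription factor of lipid synthesis, by 0.32 (SE 0.05). In this comparison the immediate early list had 4 members that fell and 2 that rose (camera adjusted p = 4.6e-06, lower), or 10 and 3 adjusted over the list alone. The ERK feedback list had 2 that fell, or 4 that fell and 1 that rose adjusted over the list alone (adjusted p = 1.1e-05, lower). Both had an adjusted p of 0.83 with an estimated correlation.

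**Figure D2:**
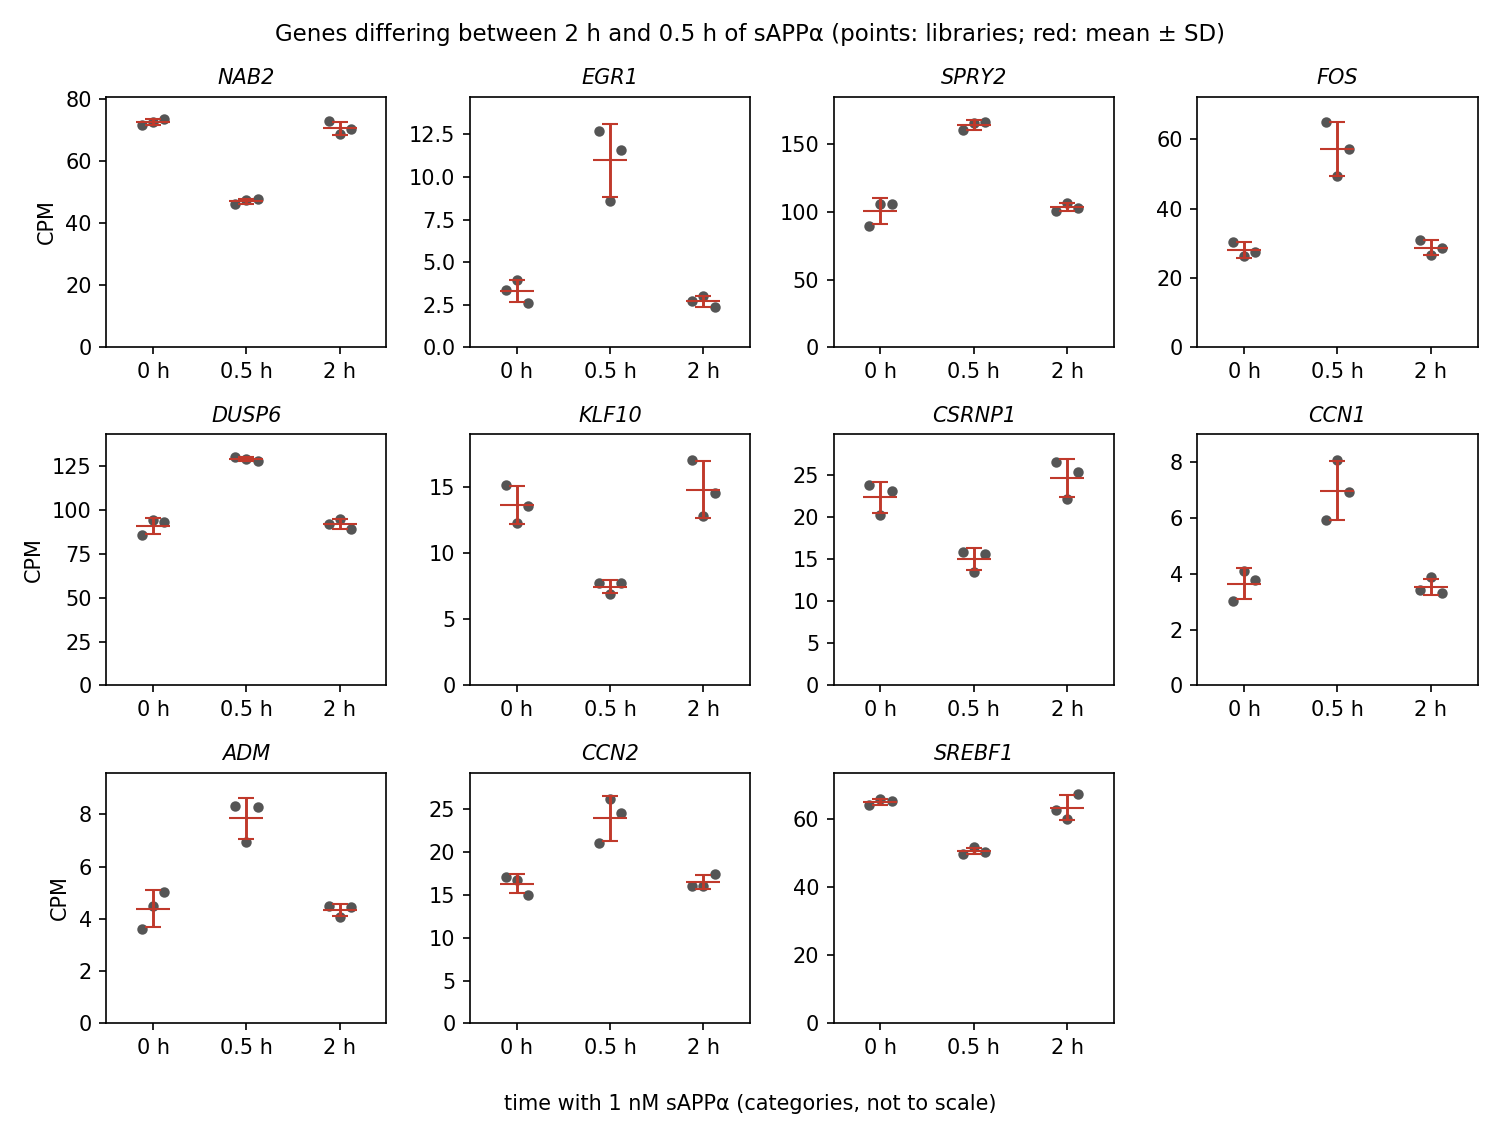
CPM (vertical axis, from 0) at 0 h, 0.5 h and 2 h of sAPPα (horizontal axis) for the 11 genes that differed between 2 h and 0.5 h, with each point a library and red bars the mean ± SD of 3 libraries. EGR1, SPRY2, FOS, DUSP6, CCN1, ADM and CCN2 were highest at 0.5 h, and NAB2, KLF10, CSRNP1 and SREBF1 were lowest there.

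Between 0.5 h and 2 h camera called 8 further lists with no called member, and none of these calls held with an estimated correlation (adjusted p from 0.83 to 0.89 with an estimated correlation). Heat shock genes (median log2 -0.07), presynaptic vesicle release (-0.04) and unfolded protein response genes (-0.04) were called lower at 2 h. Cholesterol synthesis (0.07), spliceosome (0.07), circadian (0.09), cell cycle (0.09) and pluripotency marker genes (0.14) were called higher. In the cholesterol list 21 of 24 members had a positive value, with INSIG1 at log2 0.22 (SE 0.05) and MVK at 0.21 (SE 0.05). TEF had log2 0.42 (SE 0.08, adjusted p = 0.077), and HSPA1A had -0.19 (SE 0.05). All 27 cell cycle genes had a positive value. Adjusted over the list alone, 5 heat shock genes fell, and 3 cholesterol, 1 spliceosome, 1 circadian and 1 pluripotency gene rose. The count of 11 became 7 without 2 h replicate 3 and 7 without 0.5 h replicate 3, and EGR1, FOS, SPRY2, DUSP6, NAB2, KLF10 and CSRNP1 were called whichever library was left out.

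No gene was called both at 0.5 h and at 2 h, and with 0 calls at 2 h the number expected for independent lists was 0 in each direction. With DESeq2 84 lower genes were shared (1.72 expected for independent lists), and with the replicate number as a block 90 (2.42 expected). The edgeR overlap was 29 without 0 h replicate 3, 36 without 2 h replicate 1, 1 without 2 h replicate 3 and 8 without 0.5 h replicate 2. Of the 177 genes lower at 0.5 h, 97.7% also had a negative log2 value at 2 h, with a median of -0.25 at 2 h and -0.39 at 0.5 h. The corresponding share in 20 simulations with no effect and the same 3 shared control libraries had a median of 92.1% and a maximum of 96.6%, with median log2 values of -0.16 at 2 h and -0.39 at 0.5 h. The 41 genes higher at 0.5 h had a median log2 of 0.30 at 0.5 h and 0.05 at 2 h. The simulated medians were 0.42 at 0.5 h and 0.26 at 2 h, so the simulated genes started from a larger change. Of these 41 genes, 87.8% had a positive log2 value at 2 h, against a simulated median of 97.6% and minimum of 90.2%. Across 16311 genes with a mean of at least 1 CPM, which are not independent replicates, the fold changes of the 2 comparisons correlated with r = 0.60, against a median of 0.51 and a maximum of 0.52 in the simulations, which share the controls too. The covariance was 0.0122, against a simulated median of 0.00835 and maximum of 0.00902. The 3 control libraries could not be split into sets of at least 2, so part of the excess may still come from sharing them. The simulations also drew each gene independently, with no correlation between genes and no structure among libraries beyond their sizes. Their ranges may therefore be too narrow for a comparison with the real data.

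**Figure D3:**
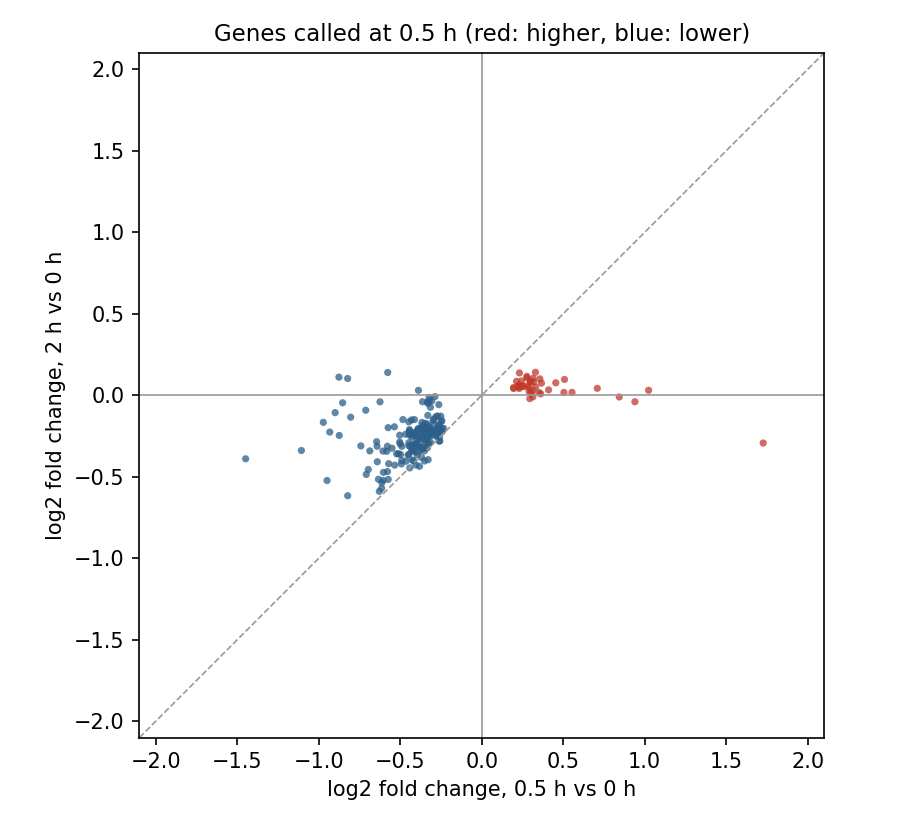
Log2 fold change at 2 h against 0 h (vertical axis) and at 0.5 h against 0 h (horizontal axis) of the 218 genes called at 0.5 h, with genes higher at 0.5 h in red, lower ones in blue and the dashed line marking equal change. The blue points have a median of -0.25 at 2 h and the red points a median of 0.05, with EGR1 at 1.73 and -0.29.

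A single test over all 3 times found 95 genes. The count depended on several libraries: it was 38 without 0 h replicate 1, 26 without 0 h replicate 2, 171 without 2 h replicate 1, 52 without 2 h replicate 3, 39 without 0.5 h replicate 1 and 17 without 0.5 h replicate 3. NAB2, SPRY2, EGR1, FOS and DUSP6 had the smallest p among them. Of 100 splits of the 9 libraries into 3 sets of 3, the real one included, 6 gave at least as many genes, up to 637.

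Markers of other cell types were measured in the same libraries. Glutamatergic neuron markers had a median of 64.8 CPM, neural progenitor markers 82.6, pluripotency markers 24.7, astrocyte markers 18.3, mesenchymal markers 9.58, peripheral neuron markers 7.46, oligodendrocyte lineage markers 3.68, GABAergic neuron markers 3.11 and microglia markers 0.319. Progenitor and astrocyte genes are also expressed in neurons to varying degrees. The 27 cell cycle genes had a median of 66.7 CPM, however, and whether progenitor or dividing cells remained in the cultures was not tested. At 0.5 h the GABAergic list was called lower by camera (median log2 -0.21, adjusted p = 0.039, and 0.85 with an estimated correlation), with no member passing and GAD2 at log2 -0.27 (SE 0.12). Its mean log2 CPM was between 1.55 and 1.59 at 0 h and between 1.32 and 1.37 at 0.5 h, with 1.30 to 1.58 at 2 h.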

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

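The tests of GC content and length, of the 0 h libraries, of single libraries and of total mitochondrial content were chosen after the results were seen, and those of chance splits, handling and rRNA depletion before.

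A set of 11 results came from the direct test of the difference between the exposures, 2 h against 0.5 h. The log2 differences were -2.02 for EGR1, -0.99 for FOS, -0.98 for CCN1, -0.85 for ADM, -0.67 for SPRY2, -0.54 for CCN2, -0.49 for DUSP6, 0.99 for KLF10, 0.72 for CSRNP1, 0.58 for NAB2 and 0.32 for SREBF1. Of these calls, 4 ended without single libraries. CCN1 had an adjusted p of 0.0536, 0.109, 0.0606 and 0.0677 without 2 h replicates 1 and 3 and 0.5 h replicates 2 and 3. CCN2 had 0.101, 0.11, 0.0887, 0.121 and 0.216 without 2 h replicates 1, 2 and 3 and 0.5 h replicates 2 and 3. ADM had 0.0525, 0.0786, 0.104, 0.0917 and 0.155 without 2 h replicates 1, 2 and 3 and 0.5 h replicates 1 and 3. SREBF1 had from 0.059 to 0.348 without 0 h replicate 3, 2 h replicates 1 and 3 or any 0.5 h replicate. Groups of 3 libraries were not tested for outlying values.

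The first pattern is the rise and return of EGR1, FOS, SPRY2, DUSP6, CCN1, CCN2 and ADM, with the opposite course in NAB2, KLF10, CSRNP1 and SREBF1. GC content and length bias is argued against as the whole cause, since with offsets for both all 11 were still called. A single aberrant library is argued against for the 7 genes called whichever library was left out. For CCN1, CCN2, ADM and SREBF1 the calls ended without some libraries (adjusted p up to 0.348). The value then moved toward 0 by at most 0.884 SE, under a bound chosen after the results were seen. Leaving out 1 of 3 libraries moves a group mean by only a part of that library's deviation, so this bound cannot decide the question for these genes. A response to sAPPα and a response to the addition of medium or to handling cannot be told apart, because 0 libraries of this series received medium without the protein, so either may be the cause. In the 10 splits of these 6 libraries, the real one called 11 genes and the highest other 27 (2 h replicate 1 with 0.5 h replicates 1 and 3), so that 2 splits called at least 11, and 10 splits are too few for a share under 0.05.

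The next pattern is the 177 genes lower at 0.5 h. With offsets for GC content and length, 128 were still called lower, and the median log2 change of all 177 went from -0.39 (quartiles -0.49 and -0.32) to -0.35 (-0.46 and -0.29), which argues against this bias as the whole cause, while a part of the calls may come from it, since their median GC content was 50.7% against 47.9% for all tested genes. The 0 h libraries standing apart and a decrease that lasted to 2 h cannot be told apart, since both put the genes below 0 at 2 h, as 97.7% of them were, and this series holds no other 0 h libraries. Of the 10 splits of the 6 libraries, only the real one, 1 split, called as many as 218 genes, and the highest other called 11, but 10 splits are too few for a share under 0.05. For 2 h against 0 h the real split called 0 genes and the highest other 1. All 10 splits called at least as many, but no split can call fewer than 0, so this count shows nothing.

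The last pattern is the mitochondrial rRNA share of 0.539% in 0.5 h replicate 3, 4.61 times the median of the other libraries. More mitochondrial RNA in that sample is argued against, since the other mitochondrial genes were at 0.952 times the median of the other libraries, within their range. Less complete rRNA depletion stays open: nuclear-encoded rRNA genes were at 1.01 times the median, but only 198 to 262 counts per library fell on them because reads matching several places were not counted, so the bound set in advance was wrong and the test shows nothing. No biological explanation was tested.

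For the test over the 3 times, chance could not be excluded: 6 of 100 splits drawn from 280 called at least 95 genes. The highest, 637, was the split by replicate number. Of the 5 splits apart from the real one that reached 95, 4, the split by number included, kept the replicates numbered 2 together, which points to a structure of the samples by number. With the replicate number as a block the count was 523.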

How the results depend on the processing

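The offsets for GC content and length, alone and with the replicate block, the omission of mitochondrial, 7SL and U3 genes, the halved counts and the omission of both libraries with high mitochondrial rRNA were chosen after the results were seen. No named gene that passed reversed, but the balance of calls did turn: of the 0.5 h calls 81.2% were lower, against 64.7% with the block and 45.3% with offsets and block (751 higher, 621 lower), and of the calls for 2 h against 0.5 h (4 higher, 7 lower) more were higher with DESeq2 (22 and 19) and without a filter (43 and 34). Of the values of 194 named results under the alternatives, 3620 kept their direction and side of the threshold, 214 no longer passed, 193 newly passed and 33 that passed in neither case changed sign.

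For 0.5 h against 0 h (218) the count was 667 with DESeq2, 130 with limma-voom, 764 without a filter, 936 with the block, 33 at an adjusted p of 0.01, 1372 with offsets and block, and 38 without both libraries with high mitochondrial rRNA. For 2 h against 0 h (0 with edgeR, 1460 at an unadjusted p under 0.05) it was 1 with DESeq2 size factors, 92 with DESeq2, 0 with limma-voom, 211 without a filter, 104 with the block (97.1% lower), 4 with offsets, 83 with offsets and block, 1 without mitochondrial, 7SL and U3 genes, and 7 without both libraries. For 2 h against 0.5 h (11) it was 41 with DESeq2, 77 without a filter, 64 with the block, 100.0 with offsets and block, and 7 without both libraries. Over the 3 times (95) it was 469 with DESeq2, 49 with limma-voom, 640 without a filter, 523 with the block, 19 at an adjusted p of 0.01, 748 with offsets and block, and 28 without both libraries. The overlap (0) was 84 with DESeq2, 90 with the block, 4 with offsets and 78 with offsets and block. Leaving out 1 library gave 45 to 275, 0 to 40, 7 to 15, 17 to 171 and 0 to 36 for these 5 counts. Of 33 list calls, 0 held with an estimated correlation and fry called 0, while 31 held with DESeq2 size factors, 28 with the block and 22 with offsets. Without a filter 47410 genes were tested and the median prior degrees of freedom became infinite, so that for the median gene the trend replaced its own spread. For all these changes the cause was not tested.

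The labels do not say what the numbers stand for. Of 9 pairs of libraries with the same number, 3 had a correlation over 0.1 (range -0.0357 to 0.149), so the numbers were not taken to pair the samples. Pairs of numbers 1 and 2 nevertheless had correlations from 0.0708 to 0.149, above the highest value for pairs with different numbers (0.0602). Those of number 3 reached at most 0.0240. The main counts leave this structure out. As a hint from the data, not the design, 6 of 9 libraries correlated best with their own number, the first principal component (17.1% of the variance) put replicate 2 of each time (15.02 to 36.9) apart from the others (-24.2 to 0.919), and the block lowered the biological coefficient of variation from 8.23% to 6.06%. At 57853197 to 77773590 counts per library, genes changed 1.2-fold were mostly missed in simulated data (11.2% recovered at 0.5 h).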

Other observations

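DUSP10, BACH2, RAB3B and PSMD12 were chosen after their values were seen. DUSP10, a phosphatase of the stress-activated kinases JNK and p38, rose at 0.5 h from 61.5 ± 5.61 to 84.4 ± 2.32 CPM (log2 0.45, SE 0.07, n = 3). Among 30 delayed activity response genes none rose and 2 fell at 0.5 h, NPTX1 (log2 -0.26) and BACH2, a transcriptional repressor (log2 -0.35, SE 0.06). Adjusted over the list alone, 2 rose and 2 fell, and camera made no call (adjusted p = 0.995). RAB3B, a small GTPase of secretory vesicles, was the only one of 50 presynaptic genes that fell (log2 -0.26, SE 0.06), and PSMD12, a regulatory subunit of the proteasome, the only one of 36 proteasome genes (log2 -0.25, SE 0.05).

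Of 27 cell cycle genes, 2 had a positive log2 value at 0.5 h against 0 h (median -0.09, camera adjusted p = 0.057, and 0.96 with an estimated correlation), and no member passed. At 0.5 h, fry found change in either direction in the immediate early list (adjusted p = 6.4e-08), the circadian list (9.9e-08), the heat shock list (4.4e-06) and the ERK feedback list (0.00017). It also did so for NF-κB targets (0.0028), cholesterol synthesis (0.0030), AMPA receptor trafficking (0.0032), postsynaptic density (0.0086), insulin and mTOR signalling (0.013), delayed activity response (0.021) and histone acetylation and methylation enzymes (0.031). This test asks whether members of a list changed at all, not whether they changed more than other genes. Of all 25271 genes, 3176 had an unadjusted p under 0.05 in edgeR at 0.5 h, where 1264 would be expected by chance. No list passed fry's test of movement on balance in 1 direction (smallest adjusted p 0.10).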
